A study of Homo sapiens with 5 samples.

How the data were processed

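RNA sequencing of total RNA from MCF7 cells was analysed in 5 libraries, 2 of the parental line and 3 of a line with acquired resistance to 6 µM siramesine. MCF7 is an established human breast cancer line of the luminal, estrogen receptor positive type. Siramesine is a cationic amphiphilic drug and a sigma receptor ligand that accumulates in lysosomes. Per the labels' protocols, cells were grown in DMEM with fetal calf serum, RNA was extracted with Trizol and libraries were made by the standard Illumina procedure.

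Each of the deposited files gives a gene name and 1 value, RPKM per the file headers, computed by the authors per kilobase of gene model and by library total in each library separately. The build hg38 is named in the submitters' processing notes. The aligner, the counting program and their settings are not given in the sources used here. The files are of 2 kinds that list different gene models. The files of parental replicate 1 and resistant replicate 1 list 36036 names and are called the smaller gene model below. The files of parental replicate 2 and resistant replicates 2 and 3 list 60448 names and are called the larger gene model. The 24624 names listed in both were used for the comparison. The remaining 35824 names of the larger model were compared within those 3 libraries alone, and the 11412 names found only in the smaller model were not used here.

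The files hold no counts, so the count model planned for counts was replaced by the test fixed beforehand for RPKM. Depth was recovered from the values themselves: low RPKM values are whole multiples of what 1 read is worth, and the commonest step of a library gives the total it was divided by. These totals were 138586568 and 169300806 for parental 1 and resistant 1, and 22786158, 22034650 and 23354461 for parental 2, resistant 2 and resistant 3. With them, all names above 0 in at least 2 libraries of a file kind gave whole numbers of reads (a common denominator of at most 200000 bases), against 12.7% and 10.0% when 1 total was shifted. Whether the unit counted was a read or a fragment is unknown, and a gene's number is known up to a common whole factor. For some genes the recovered number is therefore too low in a file kind, and limma-voom, which weights by reads, weights them wrongly. HIST1H2AG, for instance, had 29 recovered reads in parental 1 at 2.52 RPKM but 95 in parental 2 at 1.85 RPKM. In a gene of 2 kb, 1 read was worth 0.0036 RPKM in parental 1 and 0.0219 RPKM in parental 2, so low genes were measured more precisely in the smaller-model libraries. Such depth figures cover counting error only.

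Genes with at least 1 RPKM in at least 2 libraries were tested, 10229 in all. log2(RPKM + 1) was fitted with limma 3.58.1 (R 4.3.3, empirical Bayes with a mean-variance trend) with terms for the file kind and the group, which leaves 2 residual degrees of freedom per gene. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Changes are resistant minus parental on the log2(RPKM + 1) scale, which understates the change of low genes, and are given ± SE with n = 2 parental and n = 3 resistant libraries. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Resistant 2 and resistant 3 were checked for being 1 library deposited again: their recovered reads differed by more than sampling noise (mean chi-square per gene 16.9), so both were kept. Leaving out a library can leave an arm of a file kind with 1 library, which is then assumed to vary like the others. In the larger-model libraries alone, in fits without parental 1, parental 2 or resistant 1, and in tests for a difference between the file kinds, the spread comes only from resistant 2 against resistant 3.

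The 33 gene lists, the named genes and most alternatives were fixed before the data were examined. Named genes are the 12 largest changes in each direction among genes past the threshold with a mean log2(RPKM + 1) of at least 2 and a change of the same direction in every resistant library, up to 4 changed members of each list with the largest change, and 21 genes always reported. The rule had been written for log2 CPM and was applied to log2(RPKM + 1). Lists with at least 3 measured members (31) were tested with camera (limma), with a preset inter-gene correlation of 0.01 and with an estimated one, adjusted over the lists. With an estimated correlation camera refers its statistic to the residual degrees of freedom, here 2, so hardly any list could pass. A call lost there does not show that correlation between genes had made it. Counts of list members adjusted over the list alone are given beside those adjusted over all genes. GC content and exon length came from GENCODE 29 (GRCh38), which also gave positions, and were available for 99.6% of tested genes. Genes were joined by name. Older symbols were used to find list members and the position, GC content and length of genes. The list member GBA1, named GBA in both gene models, was not found this way.

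The fit was tested on simulated data before use, with the means and residual spread of these 10229 genes and 200 changed genes. Of 67 genes changed by 1 on the log2 scale 43.3% were called, of 66 changed by 2 75.8%, and of 67 changed by 0.5 0, with 0 false calls among 79. The simulated noise was independent for each gene and library, without shared trends such as that on GC content. The rate of false calls in these data can therefore be higher. Alternatives were other scalings, limma-voom on the recovered reads, other filters, another pseudocount, no file kind term, the replicate number as a block, the larger-model libraries alone and each library left out. Some of these repeat a comparison. Fits without parental 1 or without resistant 1 give the same changes as the larger-model libraries alone. The replicate block gives the same changes as leaving out resistant 3. Removal of each library's trend on GC content and length, quantile normalization and joining of names through older symbols were added after the data had been seen. No count method other than limma-voom was run. Python 3.11.15 was used for reading the files and matplotlib 3.10.9 for the figures.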

Results

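Gene expression was compared between parental MCF7 cells (2 libraries) and MCF7 cells that had acquired resistance to 6 µM siramesine (3 libraries), to describe the transcriptional changes that accompany resistance to a lysosome-targeting cationic amphiphilic drug. Parental 1 and resistant 1 were deposited with a smaller gene model and totals of 138586568 and 169300806 reads, and parental 2, resistant 2 and resistant 3 with a larger gene model and totals of 22786158, 22034650 and 23354461 reads. The first principal component, with 87.6% of the variance, separated the 2 file kinds, which differ in depth and replicate number as well as in gene model, and the second, with 8.49%, separated resistant from parental libraries. The correlation of log2(RPKM + 1) across genes was 0.972 between parental 1 and resistant 1, 0.977 and 0.978 between parental 2 and the resistant libraries of its kind, 0.994 between resistant 2 and 3, and 0.879 to 0.898 between libraries of different kinds. Each comparison below therefore sets resistant against parental cells within file kind.

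Resistant cells had 245 genes higher and 378 lower than parental cells among 10229 tested, and 83 of the former and 102 of the latter moved by more than 1 on the log2 scale. Without parental 2 the majority turned, with 761 genes higher and 641 lower. The median change over all tested genes was 0.01 (0.11 in the smaller-model pair and -0.06 in the larger-model libraries). All 623 changed genes moved in the same direction in resistant 1, 2 and 3, which their selection favours. Over all tested genes 55.1% changed in the same direction in both file kinds. Across genes, which are not independent replicates, the change correlated with GC content at a Spearman coefficient of -0.58 in the smaller-model pair. It was 0.01 for the mean of resistant 2 and 3 against parental 2, and the coefficients with length were 0.18 and 0.02. The difference between resistant 2 and resistant 3, libraries of the same group and file kind, correlated with GC content at -0.38. Trends of these libraries can therefore cancel in their mean. Genes that fell had a median GC content of 57.5%, genes that rose 47.5% and all tested genes 49.0%. With the trends on GC content and length removed together, 358 genes were higher and 350 lower, the share of higher genes was 50.6% against 39.3%, and 521 of the 623 calls were kept. Without the file kind term limma called 0 genes (282 at an unadjusted p under 0.05).

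**Figure D1:**
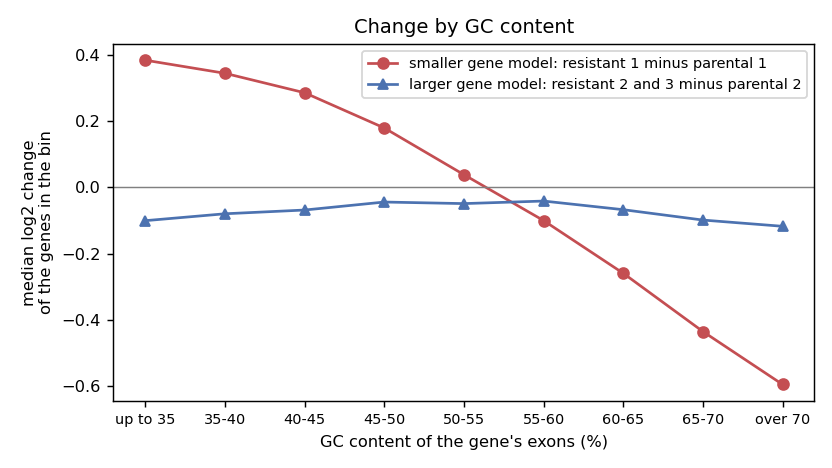
Median change (resistant minus parental, log2(RPKM + 1), vertical axis) of the genes in bins of exon GC content (horizontal axis, %), for the smaller-model pair (circles) and the larger-model libraries (triangles). In the smaller-model pair the median falls from 0.38 in the bin of lowest GC content to -0.59 in the bin of highest, whereas the larger-model medians lie between -0.12 and -0.04.

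Among changed genes with a mean log2(RPKM + 1) of at least 2, the 12 that rose most encode proteins of several kinds. PLCXD3, which encodes a phospholipase C domain protein (chromosome 5, 41306954 to 41510628), rose by 2.61 ± 0.21 (adjusted p = 0.000245), from 1.62 to 11.8 RPKM in the smaller-model pair and from 1.96 to 25.2 and 16.2 RPKM in the larger-model libraries. The growth hormone receptor gene GHR, on the same chromosome, rose by 2.21 ± 0.17. IFI44, an interferon-stimulated gene on chromosome 1, rose by 2.31 ± 0.19, and CSTA, which encodes the cysteine protease inhibitor cystatin A, by 2.15 ± 0.28, from 0.288 RPKM in parental 2 to 2.88 and 2.46 RPKM. BAMBI, a decoy receptor that dampens TGF-beta and BMP signalling, rose by 2.07 ± 0.18 and was 6.08 times as high in resistant 1 as in parental 1. FABP5, a fatty acid binding protein, rose by 1.78 ± 0.15 and PHLDA1 by 1.77 ± 0.17. PALM3 rose by 1.67 ± 0.21. The remaining 4 of these 12 all lie in a single stretch of chromosome 1. They were BTG2, an antiproliferative p53 target (1.79 ± 0.22), LAD1, a basement membrane anchoring protein (1.64 ± 0.13), CYB5R1 (1.60 ± 0.14) and GOLT1A (1.57 ± 0.21).

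MDK, which encodes the heparin-binding growth factor midkine (chromosome 11, 46380756 to 46383837), fell by 2.48 ± 0.14 (adjusted p = 7.96e-05), from 37.6 to 6.60 RPKM in the smaller-model pair and from 21.6 to 2.52 and 3.08 RPKM in the larger-model libraries. The ligand BMP7 fell by 1.91 ± 0.19, from 409 to 78.0 RPKM and from 199 to 64.1 and 69.0 RPKM, and the BMP-binding protein gene BMPER by 2.04 ± 0.21. TFF3, a secreted trefoil peptide induced by estrogen, fell by 2.23 ± 0.20, and MUC5B, a gel-forming mucin, was at -1.82 ± 0.26. PXDN, a peroxidase that crosslinks collagen IV, fell by 2.20 ± 0.14, and the calcium-binding protein gene CALB2 by 2.12 ± 0.16. SLC26A2, a sulfate transporter gene, fell by 2.04 ± 0.15 and ATP1B1, which encodes the beta subunit of the sodium pump, by 1.84 ± 0.13. The adhesion molecules CDH18 and AMIGO2 fell by 1.87 ± 0.20 and 1.80 ± 0.13, and the transcriptional corepressor gene CBFA2T3 by 1.70 ± 0.18. These 24 genes kept their calls in each of the 14 alternative settings that called any gene and tested them, which are not 14 separate comparisons.

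**Figure D2:**
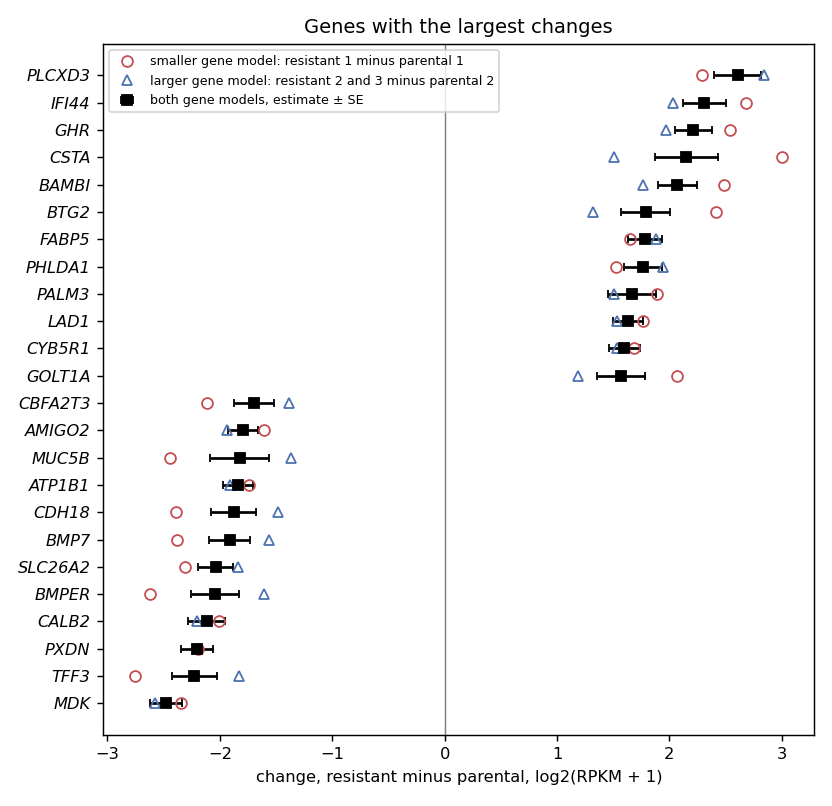
Change (resistant minus parental, log2(RPKM + 1), horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall. Only changed genes with a mean log2(RPKM + 1) of at least 2 and the same direction in every resistant library were ranked. Squares give the estimate from all 5 libraries with its SE, circles the smaller-model pair and triangles the mean of resistant 2 and 3 minus parental 2, and for each gene all of them lie on the same side of 0, for instance at 2.61, 2.29 and 2.84 for PLCXD3.

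Of 39 measured members of the estrogen response list 10 were lower, 2 higher and 27 not past the threshold (17 lower and 3 higher adjusted over the list alone), with a median change of -0.19 and a camera adjusted p = 0.00158 (adjusted p = 0.737 with an estimated correlation). PGR, the progesterone receptor gene, fell by 1.70 ± 0.12 (adjusted p = 0.000198), from 2.49 to 0.067 RPKM and from 2.91 to 0.230 and 0.197 RPKM. The calcitonin receptor gene CALCR fell by 2.18 ± 0.12, from 3.20 and 3.95 RPKM in parental 1 and 2 to 0.031 RPKM in resistant 1 and 0.021 RPKM in resistant 3, and was listed at 0 in resistant 2. TFF1, the classical estrogen-induced trefoil peptide gene, was at -1.41 ± 0.32, and CTSD, which encodes the lysosomal protease cathepsin D, was at -1.27 ± 0.30, both past the threshold. Of the members that rose, HSPB8, a small heat shock protein, rose by 1.24 ± 0.13. The estrogen receptor gene ESR1 itself was at -0.12 ± 0.14 (adjusted p = 0.702) and GREB1 at -0.50 ± 0.19 (adjusted p = 0.172). In the smaller-model pair ESR1 was at -0.32 and GREB1 at -0.98, against 0.03 and -0.14 in the larger-model libraries. The list's median was -0.46 in the smaller-model pair and -0.14 in the larger-model libraries, and the list call ended in the larger-model libraries alone (adjusted p = 0.990) and without parental 1 (adjusted p = 0.950) or resistant 1 (0.958). The calls of TFF1 (-0.79) and CTSD (-0.64) ended there too, and with median-of-ratios scaling, and that of TFF1 with quantile normalization. Without parental 2 they were at -2.25 and -2.11.

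Of 30 measured members of the integrated stress response and unfolded protein response list 5 were lower, 0 higher and 25 not past the threshold (13 and 0 adjusted over the list alone, 15 members at an unadjusted p under 0.05), with a median of -0.25 and a camera adjusted p = 6.36e-06 (adjusted p = 0.452 with an estimated correlation). limma-voom called 8 members lower and 0 higher. CHAC1, a glutathione-degrading enzyme induced by ATF4, fell by 1.37 ± 0.14 (adjusted p = 0.000753), from 4.97 to 1.06 RPKM and from 2.67 to 0.441 and 0.645 RPKM. CBS, which converts homocysteine to cystathionine, fell by 1.16 ± 0.13. The cystine transporter gene SLC7A11 fell by 0.78 ± 0.17 and the pseudokinase gene TRIB3 by 0.63 ± 0.13, and SHMT2 was the remaining member that fell. The list's median was -0.23 in the smaller-model pair and -0.30 in the larger-model libraries. The call of TRIB3 ended after the GC and length trend was removed, and those of TRIB3 and SLC7A11 (-0.36) without parental 2 (TRIB3 also without resistant 2). Of 23 oxidative stress and NRF2 target genes 4 fell and 0 rose (5 and 0 adjusted over the list alone, 6 at an unadjusted p under 0.05, camera adjusted p = 0.255). limma-voom also called 4 lower and 0 higher. Beside SLC7A11 these were the lipid peroxidase gene GPX4 (-0.87 ± 0.16), G6PD, the first enzyme of the pentose phosphate pathway (-0.74 ± 0.16), and OSGIN1 (-0.73 ± 0.17), and these 3 calls ended without parental 1 or resistant 1 (G6PD also without resistant 2), where OSGIN1 was at -0.44, against -1.12 without parental 2. G6PD and OSGIN1 also lost their calls with median-of-ratios scaling, and OSGIN1 with quantile normalization.

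Of 41 measured replication-dependent histone genes 10 were higher, 0 lower and 31 not past the threshold (16 and 0 adjusted over the list alone, 21 at an unadjusted p under 0.05 in either direction, and 9 higher and 0 lower by limma-voom), with a median of 0.37 and a camera adjusted p = 6.85e-07 (adjusted p = 0.452 with an estimated correlation). HIST1H2BJ rose by 1.09 ± 0.22, HIST1H2AG by 1.01 ± 0.17, HIST1H2BC by 0.96 ± 0.19 and HIST1H2BK by 0.84 ± 0.15. Histone genes are near-identical copies, so the assignment of reads among them is uncertain. The list call ended without parental 2 (adjusted p = 0.294), as did the calls of these 4 genes, and those of HIST1H2BJ and HIST1H2BC also ended without parental 1 or resistant 1. By contrast 0 of 40 proliferation genes passed the threshold in limma (2 at an unadjusted p under 0.05, 0 by limma-voom, and 2 higher after the GC and length trend was removed), with a median of 0.04 and a camera adjusted p = 0.544. Of 77 cytosolic ribosomal protein genes only RPL14 rose, by 0.70 ± 0.14 (0 genes adjusted over the list alone, and not without parental 1 or resistant 1), and the list's camera adjusted p was 0.0535.

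Siramesine accumulates in lysosomes. Of 41 lysosomal hydrolases matched by name only CTSD passed the threshold (0 adjusted over the list alone). Of the 41, 13 had an unadjusted p under 0.05, against 2037 of all 10229 genes. The list's GBA1 is named GBA in both gene models and was not matched, so it is outside this list's counts and tests. GBA passed the threshold, lower at -0.66, and kept its call in 13 of 14 settings. limma-voom, and the fit with the GC and length trend removed, each called 1 hydrolase higher and 1 lower. Among the hydrolases the cathepsin B gene CTSB was at 0.34 ± 0.13 (adjusted p = 0.168), the acid sphingomyelinase gene SMPD1 at -0.10 ± 0.15 and the acid ceramidase gene ASAH1 at 0.16 ± 0.16. The cathepsin L gene is listed under different symbols in the 2 file kinds and, when joined through its older symbol, CTSL was at 0.26 ± 0.15 (adjusted p = 0.388). Of 31 lysosomal membrane proteins LAMP3 rose by 0.61 ± 0.14 (0 adjusted over the list alone, 4 at an unadjusted p under 0.05), a call that ended after removal of the GC and length trend and when any 1 library other than parental 2 was left out, while LAMP1 was at 0.09 ± 0.13, LAMP2 at 0.20 ± 0.12 and the cholesterol exporter gene NPC1 at 0.08 ± 0.14. Of 21 V-ATPase subunits, which acidify the lysosome, ATP6V0A4 (1.04 ± 0.25) and ATP6V0E2 (0.58 ± 0.14) rose (2 adjusted over the list alone, 6 at an unadjusted p under 0.05). The call of ATP6V0A4 ended after removal of the GC and length trend and without parental 1 or resistant 1 (0.50, against 1.76 without parental 2), and that of ATP6V0E2 without any 1 of parental 2, resistant 2 and resistant 3. Of 36 autophagy genes limma called 0 (3 at an unadjusted p under 0.05, 0 by limma-voom, 0 adjusted over the list alone), and TFEB, the master regulator of lysosomal genes, lay below the filter, at 1.46 and 0.369 RPKM in parental 1 and resistant 1 and at 0.427, 0.145 and 0.152 RPKM in parental 2, resistant 2 and resistant 3. The camera adjusted p of these 4 lists lay between 0.322 and 0.894. Of 6 cathepsin inhibitor genes 1, CSTA, rose (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.995).

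Of 38 sphingolipid genes SGPP2 (1.30 ± 0.14) and SGPP1 (0.57 ± 0.14), the sphingosine phosphate phosphatases, rose and B4GALNT1, a ganglioside synthase, fell by 0.63 ± 0.13 (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0689). GBA, listed here too as GBA1, was not matched and is outside these counts and the camera test. It was lower, at -0.66, and past the threshold. The call of SGPP1 ended after removal of the GC and length trend, with median-of-ratios scaling, with quantile normalization and without any 1 of parental 2, resistant 2 and resistant 3. B4GALNT1 lost its call without resistant 2. Of 22 cholesterol biosynthesis genes HMGCS1 rose by 0.70 ± 0.18 and FDPS fell by 0.76 ± 0.13 (2 and 2 adjusted over the list alone, camera adjusted p = 0.161). HMGCS1 lay near the threshold (adjusted p = 0.0483) and lost its call when any 1 library other than resistant 3 was left out, with median-of-ratios scaling and with an RPKM minimum of 5. Of 21 genes of fatty acid synthesis and desaturation ELOVL6 (0.72 ± 0.14) and ACACB (0.65 ± 0.15) rose and the regulator gene SREBF1 fell by 0.68 ± 0.13 (2 and 2 adjusted over the list alone, camera adjusted p = 0.544). ELOVL6 lost its call without any 1 of parental 1, resistant 1 and resistant 2, and ACACB with median-of-ratios scaling and without any 1 of parental 2, resistant 2 and resistant 3. Of 9 sterol efflux genes limma called 0, also adjusted over the list alone (2 at an unadjusted p under 0.05, 0 by limma-voom, camera adjusted p = 0.956).

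Among drug targets and transporters, the sigma receptor genes did not pass the threshold, with SIGMAR1 at -0.52 ± 0.14 (adjusted p = 0.0651) and TMEM97 at 0.33 ± 0.13 (adjusted p = 0.189). Of the 4 members of that list limma called 0 (2 at an unadjusted p under 0.05, 0 by limma-voom, 1 lower adjusted over the list alone, camera adjusted p = 0.956). Of 7 ABC drug transporters limma also called 0, as it did adjusted over the list alone (2 at an unadjusted p under 0.05, 0 by limma-voom, camera adjusted p = 0.571). ABCG2 was at 0.22 ± 0.20 (0.73 in the smaller-model pair and -0.16 in the larger-model libraries) and ABCC1 at -0.23 ± 0.14. ABCB1, the classical multidrug efflux pump gene, was at most 0.008 RPKM in every library. Of 26 calcium and cAMP signalling genes 3 rose (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.956). They were the calcium release channel gene ITPR1 (1.05 ± 0.17) and the protein kinase A regulatory subunit genes PRKAR1B (0.97 ± 0.14) and PRKAR2A (0.75 ± 0.14), of which PRKAR2A lost its call without resistant 2. The purinergic channel gene P2RX4 was at -0.28 ± 0.14 (adjusted p = 0.307) and the adenylate cyclase gene ADCY1 at -0.86 ± 0.25 (adjusted p = 0.0852). ADCY1 was at -1.64 in the smaller-model pair and at -0.28 in the larger-model libraries.

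Of 29 measured members of the glycolysis and hypoxia list 2 fell and 0 rose (3 and 0 adjusted over the list alone, 11 at an unadjusted p under 0.05, 2 and 0 by limma-voom), the neuronal enolase gene ENO2 by 1.14 ± 0.20 and the oxygen-sensing hydroxylase gene EGLN3 by 0.64 ± 0.16, with a camera adjusted p = 0.000525 (adjusted p = 0.813 with an estimated correlation). The list's median was 0.09 in the smaller-model pair and -0.53 in the larger-model libraries, and 13 members were lower in the latter alone, which hold 1 parental library. Without parental 2 the list's direction turned and its call ended (adjusted p = 0.912), and the calls of ENO2 (-0.62) and EGLN3 (-0.32) ended too, that of EGLN3 also without resistant 2 or resistant 3, with a pseudocount of 0.1 and by limma-voom, which called another member.

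**Figure D3:**
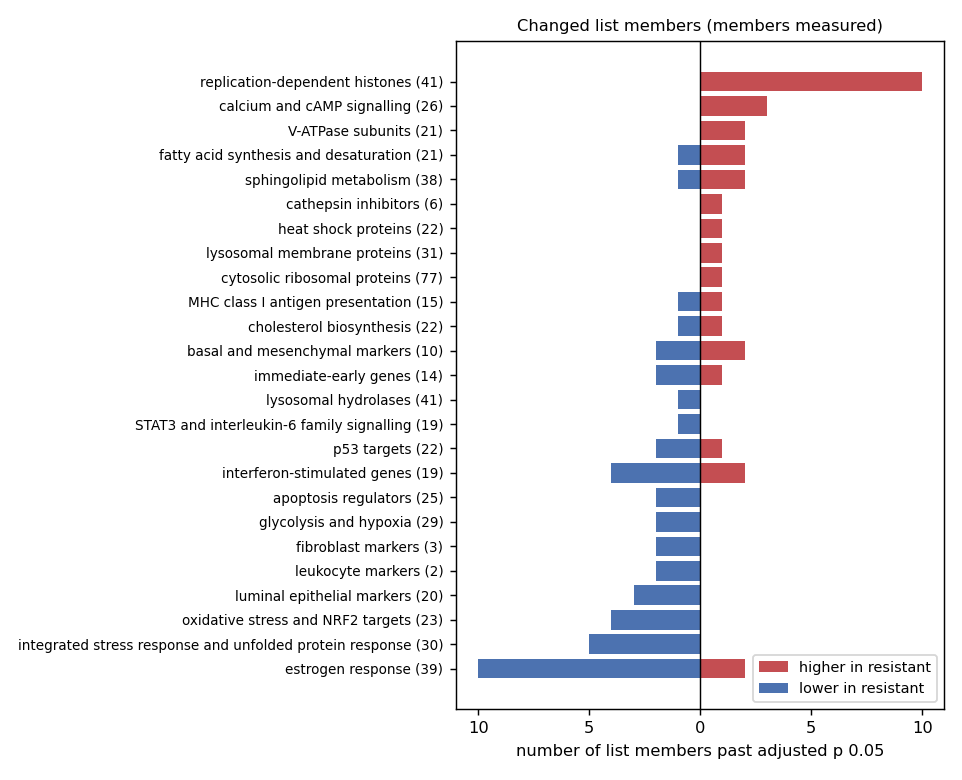
Number of members past an adjusted p of 0.05 (horizontal axis) that were higher (right) or lower (left) in resistant cells, for each list with at least 1 changed member, with the number of measured members in brackets. The longest bars are the 10 replication-dependent histone genes that rose and the 10 estrogen response genes that fell. GBA1, which was not matched to its name GBA, is not counted.

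Markers of epithelial state and of immune response shifted in part. Of 20 luminal markers 3 fell and 0 rose (3 and 0 adjusted over the list alone, 7 at an unadjusted p under 0.05, 3 and 0 by limma-voom, camera adjusted p = 0.0689): the tight junction gene CLDN3 by 0.92 ± 0.17 and the transcription factor genes SPDEF by 0.85 ± 0.15 and FOXA1 by 0.58 ± 0.13, of which SPDEF lost its call after removal of the GC and length trend. The calls of CLDN3 and SPDEF ended without parental 1 or resistant 1, those of SPDEF and FOXA1 without parental 2, and that of FOXA1 without resistant 2. Of 10 measured basal and mesenchymal markers KRT14 (1.24 ± 0.19) and CD44 (1.20 ± 0.17) rose and the integrin genes ITGB4 (-1.11 ± 0.13) and ITGA5 (-0.78 ± 0.19) fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.544). The call of ITGA5 ended after the same correction and by limma-voom, and those of KRT14 and ITGA5 (-0.30) without parental 2 (ITGA5 also without resistant 2). Of 19 interferon-stimulated genes IFI44 and IFI6 (0.94 ± 0.17) rose and 4 fell, among them IFITM2 at -1.41 ± 0.13 and IRF7 at -0.97 ± 0.13 (2 and 6 adjusted over the list alone, camera adjusted p = 0.0535). Of 15 genes of class I antigen presentation B2M rose by 0.66 ± 0.14 and HLA-C fell by 1.00 ± 0.14 (1 and 2 adjusted over the list alone, camera adjusted p = 0.911). IFI6 lost its call without parental 2, and B2M without any 1 of parental 1, resistant 1 and resistant 2. Fibroblast and leukocyte markers, which could mark other cells in a culture, were mostly below the filter. Of 3 measured fibroblast markers COL5A1 fell by 1.62 ± 0.14 and COL1A1 by 0.75 ± 0.13 (2 lower adjusted over the list alone, camera adjusted p = 0.0116, and adjusted p = 0.737 with an estimated correlation). That list call also ended without a filter on low values (camera adjusted p = 0.114). It ended too in the larger-model libraries alone and without parental 1, parental 2 or resistant 1, and the call of COL1A1 ended without resistant 2. Both measured leukocyte markers, CD68 (-1.07 ± 0.22) and CORO1A (-0.61 ± 0.14), fell (2 adjusted over the list alone), and both lost their calls after removal of the GC and length trend or without parental 2 (CD68 at -0.45). CD68 also lost its call by limma-voom, and CORO1A without any 1 of parental 1, resistant 1 and resistant 2.

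Signalling and survival genes changed individually. Of 14 immediate-early genes MYC rose by 1.03 ± 0.12 (adjusted p = 0.00154), from 20.8 to 44.0 RPKM and from 21.7 to 43.9 and 45.9 RPKM, while IER3 fell by 0.89 ± 0.14 and KLF4 by 0.84 ± 0.15 (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0689). Of 22 p53 targets BTG2 rose and BBC3 (-0.76 ± 0.16) and the cell cycle inhibitor gene CDKN1A (-0.74 ± 0.17) fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.688). Of 25 apoptosis regulators BBC3 and PMAIP1 (-0.75 ± 0.17), both proapoptotic, fell and 0 rose (2 and 0 adjusted over the list alone, 6 at an unadjusted p under 0.05, 2 and 0 by limma-voom, camera adjusted p = 0.956). The calls of BBC3, CDKN1A and PMAIP1 ended after removal of the GC and length trend, and without parental 1 or resistant 1 (PMAIP1 at -0.46, against -1.13 without parental 2). That of CDKN1A also ended with quantile normalization and without parental 2 or resistant 2. Of 19 genes of STAT3 signalling IL6R fell by 0.63 ± 0.12 and STAT3 was at -0.19 ± 0.14 (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.341), and IL6R lost its call without resistant 2. Of 22 heat shock genes HSPB8 rose, and HSPA1A was at 0.16 ± 0.18 (2 adjusted over the list alone, camera adjusted p = 0.112). limma called 0 of 11 iron handling genes (1 at an unadjusted p under 0.05, 0 by limma-voom) and 0 of 3 metallothioneins (1 and 0), and 0 of either adjusted over the list alone, with camera adjusted p-values of 0.545 and 0.890. None of the mitochondrially encoded genes could be tested in all libraries, because the smaller gene model does not list them. The median and mean of a list differed in sign for sterol efflux, sigma receptors, apoptosis regulators, cathepsin inhibitors and calcium signalling. The test followed the mean in all of these but calcium signalling, where it followed the median. For lysosomal hydrolases median and mean lay below 0 and the test pointed up.

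Several of the largest rises were neighbours on chromosome 1. Between 197.9 and 206.2 Mb, from C1orf53 to FAM72A, 35 of 53 tested genes were higher and 0 lower, which is 14.3% of all genes that rose and have a position. The median change, relative to all genes, was 1.04 in the smaller-model pair, and 0.77 in resistant 2 and 0.91 in resistant 3 against parental 2. ADIPOR1, an adiponectin receptor gene, rose by 1.44 ± 0.14, from 113 to 306 RPKM and from 110 to 287 and 317 RPKM. MDM4, an inhibitor of p53, rose by 1.08 ± 0.14, and PIK3C2B, a class II phosphoinositide kinase gene, by 1.21 ± 0.15. These 3 genes and the stretch itself were chosen after their values were seen. On chromosome 5, 13 of 21 tested genes between 37.4 and 44.8 Mb rose, PLCXD3, GHR and HMGCS1 among them, with medians of 0.72 in the smaller-model pair and 0.57 in the larger-model libraries.

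**Figure D4:**
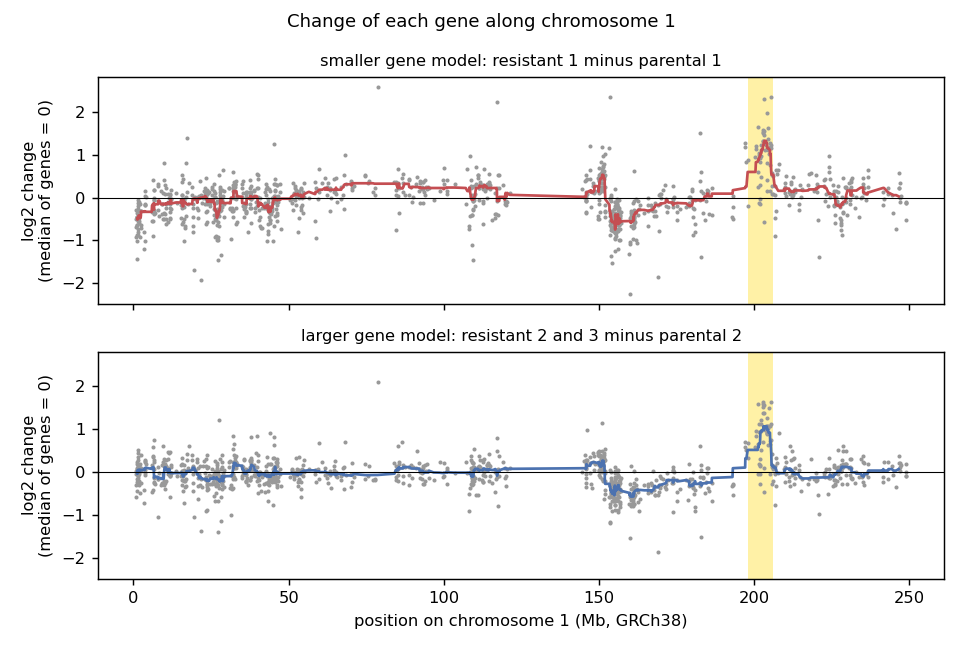
Change of each tested gene along chromosome 1 (horizontal axis, Mb, GRCh38) on the log2(RPKM + 1) scale with the median of all genes set to 0 (vertical axis), for the smaller-model pair (top) and the larger-model libraries (bottom). Dots are genes, lines are running medians over 21 genes, and the shaded stretch from 197.9 to 206.2 Mb has medians of 1.04 (top) and 0.90 (bottom).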

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

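The tests of genes and lists for a difference between the file kinds, of the names outside the shared ones and of the GC trend were chosen after the data had been seen.

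For 6 genes the change in resistant cells took opposite directions in the file kinds: each was higher in resistant 1 than in parental 1 and lower in resistant 2 and 3 than in parental 2. They were picked out by a limma interaction in which parental 1, resistant 1 and parental 2 are single libraries, so its p-values set the difference only against the spread of resistant 2 and 3. Whether it exceeds the spread between libraries of the other arms was not tested. The difference (larger-model change minus smaller-model change, log2) was -4.74 for CASP14, -3.25 for S100A8, -2.81 for NDRG1, -2.73 for CA9, -2.17 for PPFIA4 and -1.95 for ANGPTL4, with adjusted p-values of 0.00843 to 0.0468. NDRG1, CA9 and ANGPTL4 are known hypoxia-induced genes. After the GC and length trend was removed these adjusted p-values were 0.000868 to 0.0129, and 87 genes passed in all.

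By the same interaction, with the same limit, 3 lists passed the threshold as deposited and 11 after the GC and length trend was removed. The 3 were estrogen response (adjusted p = 1.31e-08), which was lower by more in the smaller-model pair, glycolysis and hypoxia (2.63e-05), with medians of 0.09 and -0.53, and replication-dependent histones (0.0125), with medians of 0.36 and 0.43. With an estimated correlation 0 of these calls held (adjusted p = 0.920 for each). That test rests on the residual degrees of freedom, fewer here than in the main fit. It could hardly call any list and does not decide the question.

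The larger-model files alone list the mitochondrially encoded genes. The summed RPKM of the 13 mitochondrial mRNAs was 1.53 times as high in resistant 2 and 1.60 times as high in resistant 3 as in parental 2, and the ratio of the resistant mean to parental 2 was between 1.30 and 2.19 for each of the 13. They took 5.49% of the library total in parental 2, 8.16% in resistant 2 and 8.71% in resistant 3. With 1 parental library limma called 0 of the 13 (lowest adjusted p = 0.108).

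Of 1076 tested names listed only in the larger-model files, limma put 3 higher and 2 lower in resistant 2 and 3 than in parental 2. With n = 1 parental and n = 2 resistant libraries the errors and adjusted p-values given here rest on resistant 2 against resistant 3 alone, and the spread of parental libraries is unknown. ADIRF was lower, at -3.31 ± 0.14 (adjusted p = 0.00248), from 105 to 10.2 and 9.14 RPKM, and SPTSSB, a small subunit of serine palmitoyltransferase, was at -1.80 ± 0.13. The noncoding RNA LINC00052 was higher by 2.05 ± 0.16, and the clone-named RP11-480I12.5 and RP11-480I12.7 by 1.64 ± 0.16 and 1.62 ± 0.16.

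The fall of GC-rich genes differed between the 2 file kinds. Across genes the change correlated with GC content at -0.58 in the smaller-model pair and 0.01 for the mean of resistant 2 and 3 against parental 2. A trend on GC content between parental 1 and resistant 1 stays open as a technical source: that correlation restates the pattern and was no test of it, but resistant 2 against resistant 3, of the same group and file kind, also gave -0.38. Removing the trends on GC content and length together raised the correlation of the changes between the kinds from 0.49 to 0.56. Counting variance came to 3.50% of the variance of the difference between the kinds, which argues against sampling of reads as its source. A difference between the resistant cultures behind the file kinds also stays open and cannot be told apart from a library effect, because the labels name 0 resistant cultures with files of both kinds.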

How the results depend on the processing

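Removal of the GC and length trend, quantile normalization and joining through older symbols were chosen after the data had been seen. Of the 623 changed genes, 285 (117 higher, 168 lower) kept their calls in all 14 settings that called any gene and tested them. Several of these settings repeat the same comparison. Of the 623, 0 changed sign in any setting, but all already had the same sign in both file kinds. Leaving out libraries could therefore hardly turn a sign. Of 80 named genes past the threshold 43 kept it in all of the 14 settings that tested them. With an RPKM minimum of 5, which tests 6938 genes, 366 genes changed (127 higher, 239 lower). Requiring an absolute log2 change above 1 left 185 (83 higher, 102 lower). Without a filter, with 16313 genes, limma called 0 (lowest adjusted p = 0.0639, 2676 at an unadjusted p under 0.05), and group alone with no file kind term also gave 0 (lowest adjusted p = 0.525, 282 at an unadjusted p under 0.05). The cause was not tested in the former. In the latter the file kind difference enters the residual spread. limma-voom on the recovered reads called 738 and the larger-model libraries alone 781.

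Leaving out 1 library gave 429 to 1402 changed genes, 169 to 761 higher and 260 to 641 lower. The highest came without parental 2 (1402, 761 higher), where parental 1 and resistant 1 alone carry the comparison, and the lowest without resistant 2. Without parental 1, parental 2 or resistant 1 the spread comes only from resistant 2 against resistant 3. The lowest limma adjusted p was 1.8e-40 without resistant 2, 8.8e-55 without resistant 3 and 3.4e-57 with the replicate block, against 5.63e-06 in the main fit. With so few residual degrees of freedom, values this small arise when variance is taken almost wholly from the trend across genes. Calls in these settings therefore say little about each gene's own spread. With the replicate number as a block in place of the file kind term, 672 genes changed (269 higher, 403 lower), and of the named calls those of LAMP3, ATP6V0E2, SGPP1, ACACB and EGLN3 ended. Resistant 3 is the only library of its number and drops out there, so the changes equal those without resistant 3. Deviations from the group means correlated at 0.88 for number 1 and 0.86 for number 2, but numbers follow the file kinds and parental 2 with resistant 3 gave 0.81, so a shared number cannot be told apart from a shared file kind.

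Of 5 lists past the threshold 0 passed with an estimated correlation, a test that 2 residual degrees of freedom left hardly able to call any list. The estimate was under the preset 0.01 for histones (-0.018), the stress response (0.00036) and fibroblast markers (-0.118), so correlation did not end those calls. It was 0.24 for estrogen response and 0.61 for glycolysis and hypoxia. Without resistant 2 and without resistant 3, 5 and 6 lists passed with the preset. The glycolysis and hypoxia list turned direction without parental 2 (adjusted p = 0.912) and stood at 7.68e-10 without resistant 1 and 9.60e-10 without parental 1. Of lists not past the threshold, ribosomal proteins passed in 9 other settings (adjusted p = 0.00168 to 0.0479, and 0.857 with an estimated correlation), interferon-stimulated genes in 7 (0.00262 to 0.0479, and 0.737), sphingolipid metabolism in 4, immediate-early genes in 2 and luminal markers in 1 (0.737 with an estimated correlation for each of these). Estrogen response did not pass in the larger-model libraries alone (0.990). The DESeq2 alternative was not run, limma-voom being the only count method applied to the recovered reads, unique-read counts are not in the files, and the smaller-model pair alone (1 against 1) gave folds with no test. Depth limits low genes mostly in the larger-model libraries, where totals were 22034650 to 23354461 reads.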

Other observations

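Tests of the chromosome 1 stretch against other runs and for copy gain, the GC and length correction, and the genes named in this paragraph and the next, were chosen after the data had been seen. The largest fall of any tested gene was that of SLC6A14, an amino acid transporter gene, at -3.63 ± 0.14, from 19.4 to 0.536 RPKM in the smaller-model pair and from 11.8 to 0.040 and 0.142 RPKM in the larger-model libraries. Genes of the extracellular matrix went both ways, and the genes named here are a selection that does not give the balance. HSPG2 (perlecan) fell by 1.60 ± 0.16, COL18A1 by 1.22 ± 0.17, COL12A1 by 1.60 ± 0.19, LAMC1 by 1.45 ± 0.16 and the sulfatase gene SULF1 by 1.77 ± 0.13. MGP rose by 1.05 ± 0.20, MATN2 by 0.94 ± 0.16, NTN4 by 0.88 ± 0.19, FRAS1 by 0.70 ± 0.12 and LAMA3 by 0.57 ± 0.12. The call of MGP ended without parental 2, and that of LAMA3 without resistant 2 and with the replicate number as a block. The actin crosslinker gene FLNA fell by 1.60 ± 0.17. GFRA1 and SCUBE2, commonly expressed in estrogen receptor positive tumours, fell by 1.55 ± 0.16 and 1.54 ± 0.18. No list of matrix genes was fixed beforehand and no enrichment was tested.

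Genes of lipid handling also went both ways, and no list of them was fixed beyond those reported. MGLL, a monoacylglycerol lipase gene, rose by 1.26 ± 0.15 (adjusted p = 0.00141), the fatty acid transporter gene CD36 by 1.36 ± 0.29 and the steroid sulfatase gene STS by 1.52 ± 0.19. OXCT1, a ketone body enzyme gene within the chromosome 5 stretch, rose by 1.21 ± 0.14. CRAT, a carnitine acetyltransferase gene, fell by 1.42 ± 0.15, the peroxisomal oxidase gene ACOX2 by 1.18 ± 0.21, the thioesterase gene ACOT2 by 0.76 ± 0.15 and the lipid droplet gene PLIN3 by 0.70 ± 0.14. The call of ACOX2 ended without parental 1 or resistant 1 and in the larger-model libraries alone, that of ACOT2 without parental 2 or resistant 1, and that of PLIN3 without parental 2 or resistant 2 and after the GC and length trend was removed. The C-type lectin gene CLEC3A rose by 2.24 ± 0.13, from 0.052 to 4.05 RPKM and from 0.321 to 4.89 and 5.52 RPKM.

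The genes between 197.9 and 206.2 Mb of chromosome 1 were high in resistant cells as a block. The block was found in the smaller-model pair and then read in the other libraries, where 0% of 8887 other runs of 53 consecutive genes reached its median of 0.90 (the highest was 0.29), which argues against a run of this height by chance. After the trend on GC content and length was removed the median was still 1.04 in the smaller-model pair, which argues against that trend as the whole cause. In the larger-model libraries it was 0.89. Their mean change had hardly any such trend to remove (Spearman 0.01 with GC content), so that value could not test the trend. A gain of DNA copies in the resistant line is a candidate explanation, as 88.7% of the 53 genes lay above 0 in the larger-model libraries, but DNA was not measured and a shared regulatory change of the region was not tested.

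Of 21 runs of neighbouring genes found in the smaller-model pair 3 were higher and 18 lower. After the GC and length trend was removed 3 were found, all higher, 2 of them on chromosome 1 and 1 on chromosome 5. Genes between 153947669 and 155289848 of chromosome 1 (39 genes, CRTC2 to HCN3) had a median of -0.59 in the smaller-model pair and -0.46 in the larger-model libraries, with 92.3% of genes below 0 in the latter. After the correction these medians were -0.42 and -0.47, and this run was not among those found. The next 3 runs along the chromosome, up to 161 Mb, were also lower in both file kinds. Their medians were -0.17 and -0.37 (7 genes, YY1AP1 to ARHGEF2), -0.41 and -0.33 (10 genes, SLC25A44 to IQGAP3) and -0.55 and -0.49 (23 genes, GPATCH4 to USF1, 95.7% below 0 in the larger-model libraries), in the smaller-model pair and the larger-model libraries in turn. After the correction these medians were -0.15 and -0.38, -0.24 and -0.32, and -0.45 and -0.51.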
